A study of Mus musculus with 16 samples.

How the data were processed

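RNA from mouse bone marrow was hybridised to 16 oligonucleotide arrays after biotin labelling. The labels place 6 arrays in Bank1+/- Pax5+/- leukemia (written Bank1/Pax5 leukemia), 6 in Pax5+/- leukemia (written Pax5 leukemia) and 4 in wild-type (WT) pro-B and pre-B cells. Per the labels, the authors processed the arrays with RMA through the oligo package, without stated versions, and the deposited values are log2 probe set intensities. They were used without further scaling. Background and filter settings are not given in the sources used here, nor are hybridisation batches. Array medians over all probe sets lay between 6.58 and 6.71 log2, and values between 3.82 and 14.3. For arrays the number of arrays limits the precision.

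Of 35556 probe sets, 21789 named 1 gene, 1621 named several and 12146 named none in the annotation used. Gene symbols were updated through their gene records, except for 91 probe sets without a current record. For the 999 genes with more than 1 probe set, the one with the highest mean over all arrays was kept, which left 19938 genes. Probe sets naming several genes or none were left out of the comparisons. No genome build is stated for the array, so no coordinates are given.

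One linear model with a mean for each of the 3 groups was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation. The contrasts were each leukemia group minus WT, and Bank1/Pax5 minus Pax5 leukemia. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison, and SE denotes the moderated standard error. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, adjusted over the 26 lists of a comparison, and again with an estimated correlation. For lists that passed, calls adjusted over the list alone are given beside those over all genes. A gene with a group mean under 7.02, the median of named probe sets, is called dim in that group, and the size of its difference is not well bounded. The level of a list on an array is the median log2 value of its measured genes.

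The lists were Pax5-activated genes, Pax5-repressed genes, pro-B and pre-B stage genes, mature B cell genes, B cell receptor signalling, IL-7 receptor with JAK-STAT and survival, cell cycle, MYC targets and ribosome biogenesis, p53 response, leukemia suppressor genes, interferon response, NF-kB and inflammatory genes, glycolysis, oxidative phosphorylation, immediate early and stress genes, and markers of neutrophils, monocytes and macrophages, erythroid cells, megakaryocytes, T cells, NK cells, plasma cells, dendritic cells, mast cells with basophils and eosinophils, stromal and endothelial cells, and stem and progenitor cells. Of their 460 places, 420 were measured. Sex-linked genes and immunoglobulin segments were described without a list test. The named genes were Bank1 and Pax5, the 10 called genes with the largest difference in each direction of a comparison, and up to 4 list members with the smallest p. Immunoglobulin and T cell receptor segments, uncharacterised genes and small RNAs were left out of these top genes. Groups, contrasts, tests, lists and the rule for named genes were fixed before the data were examined. Small nucleolar RNAs (snoRNAs) were taken up as a group only after their values were seen.

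The alternative settings were a filter on dim probe sets, other ways to combine probe sets, cyclic loess, median centring, a variance trend with robust moderation, array weights, only the 2 groups compared, the replicate number as a block, a 2-fold minimum, an estimated correlation and leaving out each array in turn. Settings chosen after seeing the data were a covariate of Y-linked genes, a covariate of the mean of 8 non-B marker lists, leaving out the 3 leukemia arrays with a Pax5 level under 9, and leaving out short RNAs.

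The fit assumes 1 spread per gene for all groups, yet the median gene SD was 0.180 log2 in Bank1/Pax5 leukemia, 0.159 in Pax5 leukemia and 0.0866 in WT. The procedure was tested on simulated data, with 10 simulations of 200 changed genes for each contrast. With 1 spread per gene, 5.2%, 5.1% and 4.9% of calls were false for Pax5 leukemia minus WT, Bank1/Pax5 leukemia minus WT and the contrast of the leukemia groups. With each group's own spread these shares were 4.3%, 7.2% and 20.9%. A fit of the leukemia groups without WT gave 8.5% with each group's own spread and 5.3% with 1 spread, so calls from that fit stand beside the planned ones. At a true log2 difference of 1, the planned fit recovered 82.4%, 82.1% and 84.3% of changed genes under each group's own spread. A list shifted by 0.5 was called in 10 of 10 such simulations for each contrast. Of 250 tests of other lists, 1, 3 and 0 were called. Genes were drawn independently of each other, so these simulations cannot show how often the list test errs when genes are correlated.

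Differences in an array-level measure were tested by exact two-sided permutation of the arrays. Correlations over 12 arrays used 100000 permutations. Intervals of a list's median came from resampling its genes, and genes are not independent replicates. The shared use of the WT arrays by both comparisons against them was examined by 100 simulations of unchanged groups and by splitting the WT arrays.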

Results

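The series asks what the loss of a Bank1 allele does in acute lymphoblastic leukemia of B cell precursors, a cancer of immature B cells. Expression was measured on 16 mouse arrays: 6 of leukemic bone marrow from Bank1+/- Pax5+/- mice (Bank1/Pax5 leukemia), 6 of leukemic bone marrow from Pax5+/- mice (Pax5 leukemia) and 4 of WT pro-B and pre-B cells. Per the labels the leukemic samples are total bone marrow, whereas the WT samples are a B cell precursor fraction, and the way it was isolated is not given in the sources used here. The cell type label of the WT arrays also reads as leukemic cells, against their title, source, tissue and genotype labels, and they were treated as WT precursors. The design text names 3 WT mice while 4 WT arrays carry separate replicate labels, and these were treated as 4 replicates. WT arrays correlated with each other at r from 0.992 to 0.995 across probe sets, against 0.968 to 0.982 among Pax5 leukemias and 0.944 to 0.987 among Bank1/Pax5 leukemias.

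Bank1, which encodes a B cell adaptor protein, was 2.91-fold lower in Bank1/Pax5 than in Pax5 leukemia (log2 difference -1.54, SE 0.38, adjusted p = 0.0265, 6 arrays each). Its log2 level was 8.63 ± 0.78 (SD, n = 6) in Bank1/Pax5 leukemia, 10.18 ± 0.79 (SD, n = 6) in Pax5 leukemia and 9.17 ± 0.12 (SD, n = 4) in WT cells. Against WT, Bank1 differed by 1.01 (SE 0.42, adjusted p = 0.0964) in Pax5 leukemia and by -0.53 (SE 0.42, adjusted p = 0.404) in Bank1/Pax5 leukemia, and neither passed the test. Pax5, the transcription factor that commits cells to the B lineage, was at 11.96 ± 0.12 (SD, n = 4) in WT, 10.98 ± 1.75 (SD, n = 6) in Pax5 leukemia and 9.78 ± 1.58 (SD, n = 6) in Bank1/Pax5 leukemia. Its log2 differences from WT were -0.98 (SE 0.89, adjusted p = 0.446; -0.29 without array 3 of Pax5 leukemia) and -2.18 (SE 0.89, adjusted p = 0.101), and that between the leukemia groups was -1.20 (SE 0.80, adjusted p = 0.390). In 3 leukemia arrays Pax5 was under 9: array 3 of Pax5 leukemia at 7.52 and arrays 1 and 5 of Bank1/Pax5 leukemia at 7.85 and 8.02.

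The Bank1 call between the leukemia groups ended in the fit without WT (adjusted p = 0.0815; range over all alternatives 0.00883 to 0.111), with the replicate block (0.0609), without the arrays with low Pax5 (0.0662) and with non-B markers as a covariate (0.111). In the order of these settings the log2 difference of Bank1 was -1.54, -1.54, -1.76 and -1.61. The call also ended without array 5 of Bank1/Pax5 leukemia (0.0504) or array 2 (0.0577), 4 (0.0573) or 5 (0.0579) of Pax5 leukemia. Against WT, Bank1 passed in Pax5 leukemia without its array 1 (1.28, adjusted p = 0.0189; range over all alternatives 0.00644 to 0.187), with array weights (1.13, 0.00644) and with Y-linked genes as a covariate (1.81, 0.0222). With that covariate its difference in Bank1/Pax5 leukemia turned from -0.53 to 0.0688 (adjusted p = 0.933). Pax5 passed in Bank1/Pax5 leukemia without its array 2 (-2.59, adjusted p = 0.0446; range 0.0124 to 0.225), with array weights (-2.50, 0.0124) and without the arrays with low Pax5 (-1.26, 0.0407). The arrays with low Pax5 were left out by their Pax5 level, so that last pass follows a selection on the tested gene. With non-B markers as a covariate the Pax5 difference between the leukemia groups became 0.45 (adjusted p = 0.755, range 0.0726 to 0.755). Where the probes of Bank1 and Pax5 lie relative to the targeted parts of the genes is not given, which limits what these levels say about the genotypes.

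**Figure D1:**
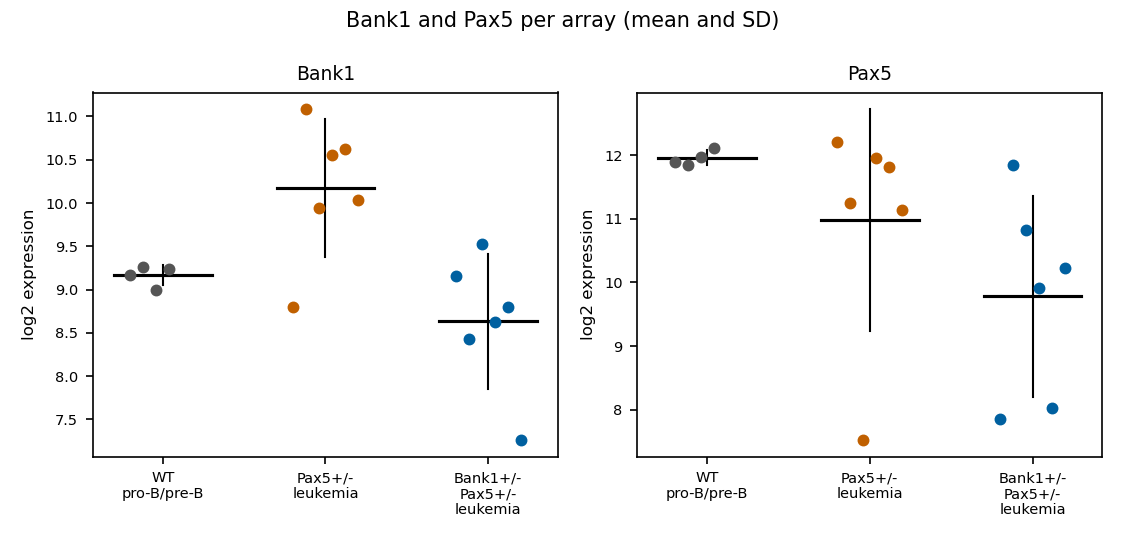
Log2 expression of Bank1 (left) and Pax5 (right) on each array, by group; points are arrays, horizontal bars are group means and vertical lines are SDs. Bank1 averaged 8.63 in Bank1/Pax5 leukemia and 10.18 in Pax5 leukemia, and Pax5 ranged from 7.52 to 12.21 in Pax5 leukemia.

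The comparison of Pax5 leukemia with WT precursors shows what set leukemic marrow of Pax5+/- mice apart from normal B cell precursors. Ppbp, which encodes a platelet chemokine, was higher in Pax5 leukemia (log2 difference 6.37, SE 0.29, adjusted p = 3.3e-09, 6 against 4 arrays). The ribonuclease gene Rnase12 rose by 5.53 on the log2 scale (SE 1.05) and Bgn, which encodes the matrix proteoglycan biglycan, rose by 4.46 (SE 0.42). Reln, the gene of reelin, fell by 4.46 on the log2 scale (SE 0.14, adjusted p = 3.15e-11), and Polm, a DNA polymerase that acts in end joining, fell by 4.04 (SE 0.11, adjusted p = 7.89e-12). The first 3 genes were dim in WT (6.22, 6.56 and 5.73), and Reln and Polm were dim in Pax5 leukemia (6.14 and 6.30). The dim level lay under the median of 7.02 of named probe sets, so the size of these changes is not well bounded. In all, 4655 of 19938 genes were called, 1901 higher and 2754 lower, and 972 of them differed at least 2-fold (560 higher, 412 lower).

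The other top genes higher in Pax5 leukemia were Sparc (4.35), Sema6d (4.24), Eif2s3y (4.22), Igfbp7 (4.08), Vcam1 (4.05), Serping1 (3.91) and Ifitm1 (3.69), as log2 differences. Those lower were the X-inactivation RNA Xist (-6.00), the B cell coreceptor gene Cd72 (-4.34), Fcrla (-4.12), Lgr5 (-4.00), Eya1 (-4.00), the NK cell receptor gene Ncr1 (-3.99), Cd7 (-3.96) and Cd2 (-3.85). Of these, the genes other than Ifitm1, Cd72, Fcrla, Cd7 and Cd2 were dim in the group with less of them. Eif2s3y lies on the Y chromosome, and all 4 WT arrays had high Xist (12.51 to 12.69) and low Eif2s3y (4.58 to 4.63). The Eif2s3y call ended without any single WT array (adjusted p from 0.0531 to 0.0632).

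Pax5-activated genes were lower as a list in Pax5 leukemia (adjusted p = 0.000266), but not with an estimated correlation (adjusted p = 0.213). Of 18 measured members 9 fell, none rose and 9 did not pass (10 fell when adjusted over the list alone). Examples are Irf4 (log2 difference -2.67, SE 0.34), Ikzf3 (-3.74, SE 0.54) and Bach2 (-3.07, SE 0.51), transcription factors of B cell development. Leukemia suppressor genes, which share some members with that list, included 9 that fell and 1 that rose of 18 (10 and 2 over the list alone; list adjusted p = 0.0190, and adjusted p = 0.213 with an estimated correlation), among them Btg1 (-1.73, SE 0.16), Rb1 (-1.50, SE 0.20) and Ikzf1 (-0.60, SE 0.10). Among pro-B and pre-B stage genes 4 of 19 fell and 1 rose, with Enpep at -3.07 (SE 0.26; dim in Pax5 leukemia), and in B cell receptor signalling 6 of 21 fell and 1 rose, with Syk at -1.44 (SE 0.21) and Pik3ap1 at -1.74 (SE 0.23). Both lists missed the test (adjusted p = 0.0511 and 0.139). Among marker lists of other cells that passed, monocyte and macrophage (median 1.57), megakaryocyte (1.86) and stromal and endothelial markers (1.74) rose. NK cell markers (-2.41) fell. Cell content and expression per cell were not separated.

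Of 20 MYC targets and ribosome biogenesis genes, 12 rose and none fell in Pax5 leukemia (17 over the list alone), led by Mybbp1a (1.37, SE 0.15), Gnl3 (1.32, SE 0.15) and Srm (1.46, SE 0.16). Myc itself rose 3.82-fold (1.93, SE 0.17, adjusted p = 3.77e-06). This list had an adjusted p of 1.32e-12, and adjusted p = 0.213 with an estimated correlation. In glycolysis 7 of 14 rose and 1 fell (9 and 2 over the list alone), including Pdk1 (1.76, SE 0.20) and Aldoa (0.96, SE 0.18), with adjusted p = 0.000507 for the list and adjusted p = 0.236 with an estimated correlation. In oxidative phosphorylation 5 of 21 rose and none fell, over the list alone as well (adjusted p = 0.00153, 0.0524 with dim probe sets removed, and adjusted p = 0.661 with an estimated correlation). Immediate early and stress genes fell, 11 of 19 with none risen (13 over the list alone): Fosb was at -1.96 (SE 0.12; dim in Pax5 leukemia), Zfp36 at -1.77 (SE 0.20) and Klf2 at -1.77 (SE 0.17). This was the only list of the comparison that held with an estimated correlation (adjusted p = 1.47e-06, and 0.0354 when estimated). The WT samples are a cell fraction and the leukemic samples total marrow. A difference in sample handling therefore cannot be told apart from leukemia for these genes.

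Monocyte and macrophage markers rose in 7 of 15 and fell in none in Pax5 leukemia (7 over the list alone; adjusted p = 6.28e-06, and adjusted p = 0.256 with an estimated correlation), with C1qb at 3.65 (SE 0.42) and Mrc1 at 2.75 (SE 0.52). Megakaryocyte markers rose in 6 of 9 (8 over the list alone; adjusted p = 1.61e-06, and adjusted p = 0.256 with an estimated correlation), including Pf4 at 3.66 (SE 0.56). Stromal and endothelial markers rose in 9 of 13 (9 over the list alone; adjusted p = 1.26e-07, and adjusted p = 0.190 with an estimated correlation). NK cell markers fell in 8 of 11 (9 over the list alone; adjusted p = 1.47e-06, and adjusted p = 0.190 with an estimated correlation), with Eomes at -2.62 (SE 0.26), Klra8 at -2.72 (SE 0.28) and Prf1 at -1.40 (SE 0.13). Of the genes named here, C1qb, Mrc1 and Pf4 were dim in WT and Eomes, Klra8 and Prf1 in Pax5 leukemia.

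The remaining lists of this comparison did not pass, with adjusted p from 0.0704 to 0.999. Members called were 3 higher and 3 lower of 15 Pax5-repressed genes, 1 and 1 of 19 mature B cell genes, 4 and 3 of 18 IL-7 receptor and survival genes, 0 and 2 of 27 cell cycle genes, 1 and 4 of 18 p53 response genes, 0 and 1 of 18 interferon genes and 3 and 7 of 22 NF-kB and inflammatory genes. Among cell markers they were 1 and 0 of 18 for neutrophils, 0 and 1 of 13 for erythroid cells, 0 and 2 of 14 for T cells, 0 and 3 of 9 for plasma cells, 0 and 1 of 9 for dendritic cells, 0 and 0 of 9 for mast cells, basophils and eosinophils, and 3 and 0 of 9 for stem and progenitor cells. The median and mean differed in sign for p53 response genes (0.08 and -0.17, test upward) and plasma cell markers (0.11 and -0.37, test downward).

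The groups did not overlap for 4948 genes, 24.8% against 0.952% by chance. The balance of directions depended on scaling, with 2021 higher and 1953 lower after median centring and 2302 and 2136 after cyclic loess, and the count was 3072 without WT array 4 and 8104 with array weights. All WT arrays carried the female pattern of sex-linked genes, cell purity differed by the labels, and 3240 genes were called with Y-linked genes as a covariate.

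The comparison of Bank1/Pax5 leukemia with WT precursors asks the same of leukemic marrow with both heterozygous genes. Ppbp was higher (log2 difference 6.84, SE 0.29, adjusted p = 1.94e-09, 6 against 4 arrays), as were Bgn (4.51, SE 0.42) and Wfdc17 (4.48, SE 0.49), all 3 dim in WT (Wfdc17 at 6.70). Cpm, which encodes carboxypeptidase M, fell by 4.76 on the log2 scale (SE 0.99, adjusted p = 0.00368) and Ikzf3, a lymphoid transcription factor, fell by 4.69 (SE 0.54, adjusted p = 3.63e-05). Reln was at -4.22 (SE 0.14) and Polm at -3.87 (SE 0.11), and Cpm, Reln and Polm were dim in Bank1/Pax5 leukemia (6.79, 6.37 and 6.46). In all, 3899 genes were called, 1356 higher and 2543 lower, with 936 at least 2-fold (505 higher, 431 lower).

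The other top genes higher in Bank1/Pax5 leukemia than WT were Vcam1 (4.41), Pf4 (4.37), C1qb (4.36), Sparc (4.30), Thbs1 (4.20), Serping1 (4.11) and Fabp4 (3.95). Those lower were Xist (-4.34), Vpreb3 (-3.90), Trib2 (-3.88), Eya1 (-3.80), Lgr5 (-3.79) and Fcrla (-3.77). Dim in the lower group were all of the higher ones but Thbs1, and Eya1 and Lgr5. The calls of Xist and of Vpreb3, a gene of pre-B cells, were narrow (adjusted p = 0.0459 and 0.0406). Leaving out any WT array, or array 1, 4 or 6 of Bank1/Pax5 leukemia, ended both (adjusted p from 0.0779 to 0.0973 for Xist and 0.0692 to 0.0897 for Vpreb3), as did leaving out array 2 for Xist (0.0724) and array 5 for Vpreb3 (0.0676). With Y-linked genes as a covariate the adjusted p of Vpreb3 was 0.253. Xist also missed with cyclic loess (0.0520) and only these groups in the fit (0.0906), and Vpreb3 without the arrays with low Pax5 (0.0956).

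Pax5-activated genes fell in 9 of 18 and rose in none in Bank1/Pax5 leukemia (11 fell over the list alone), including Spib (-2.64, SE 0.37), Irf4 (-2.35, SE 0.34) and Bach2 (-3.48, SE 0.51), with adjusted p = 3.69e-05 for the list and adjusted p = 0.128 with an estimated correlation. Pro-B and pre-B stage genes fell in 5 of 19 and rose in 1 (8 and 1 over the list alone), among them Enpep (-3.03, SE 0.26; dim in Bank1/Pax5 leukemia) and Tcf3 (-1.77, SE 0.33). That list had an adjusted p of 0.00726, 0.0585 with dim probe sets removed, and adjusted p = 0.535 with an estimated correlation. B cell receptor signalling genes fell in 6 of 21 and rose in none (8 over the list alone), including Prkcb (-1.08, SE 0.14), Syk (-1.50, SE 0.21) and Pik3ap1 (-1.60, SE 0.23), with adjusted p = 0.00273 and adjusted p = 0.0501 with an estimated correlation. Leukemia suppressor genes fell in 9 of 18 and rose in 1 (10 and 1 over the list alone; adjusted p = 0.000542, and adjusted p = 0.0840 with an estimated correlation), with Ikzf1 at -1.02 (SE 0.10) and Btg1 at -1.41 (SE 0.16). Pax5-repressed genes rose in 3 of 15 and fell in 1, over the list alone as well, with Csf1r at 2.62 (SE 0.42; dim in WT). That list had an adjusted p of 0.0115, 0.0569 with cyclic loess, 0.117 without the arrays with low Pax5, and adjusted p = 0.361 with an estimated correlation. Array 2 of Bank1/Pax5 leukemia stood apart in level, at 10.19 for Pax5-activated genes (others 8.55 to 8.91). For Pax5-repressed genes it was at 8.79 (others 10.05 to 10.45), under every WT array (9.055 to 9.474). Markers of several other cell types rose in this comparison, as given below, and NK cell markers fell. Cell content and expression per cell were not separated.

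MYC targets and ribosome biogenesis genes rose in 5 of 20 and fell in none (6 over the list alone), with Mybbp1a at 0.94 (SE 0.15) and Gnl3 at 0.82 (SE 0.15), and Myc was 2.95-fold higher (1.56, SE 0.17). The list's adjusted p was 2.17e-06, and adjusted p = 0.361 with an estimated correlation. Glycolysis genes rose in 4 of 14 with none fallen, over the list alone as well, including Pdk1 at 1.33 (SE 0.20); the adjusted p was 0.000380, and adjusted p = 0.197 with an estimated correlation. Oxidative phosphorylation genes rose in 2 of 21 and fell in 1 (1 and 1 over the list alone), with adjusted p = 0.0120, 0.0527 without array 1 of Bank1/Pax5 leukemia, 0.118 without the arrays with low Pax5, and adjusted p = 0.610 with an estimated correlation. Immediate early and stress genes fell in 9 of 19 with none risen (11 over the list alone), with Fosb at -1.92 (SE 0.12; dim in Bank1/Pax5 leukemia) and Zfp36 at -1.77 (SE 0.20), adjusted p = 1.58e-05 and adjusted p = 0.0501 with an estimated correlation. Cell cycle genes fell in 4 of 27 with none risen (3 over the list alone; adjusted p = 0.00146, and adjusted p = 0.648 with an estimated correlation), and E2f2 was at -2.14 (SE 0.46). The median level of the list was lowest on arrays 4 and 6 of Bank1/Pax5 leukemia (8.73 and 9.41), with the others at 10.47 to 10.93 and WT at 10.67 to 10.86. Interferon response genes rose in 4 of 18 with none fallen, over the list alone as well (adjusted p = 0.00146, and adjusted p = 0.535 with an estimated correlation). In level, array 2 of Bank1/Pax5 leukemia (7.15) lay under every WT array (7.61 to 7.92) and the others lay above (8.72 to 10.82).

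Among markers of other cells in the same comparison, monocyte and macrophage markers rose in 11 of 15 (12 over the list alone; adjusted p = 9.58e-10, and adjusted p = 0.128 with an estimated correlation), with Mrc1 at 3.87 (SE 0.52; dim in WT). Megakaryocyte markers rose in 8 of 9 (8 over the list alone; adjusted p = 2.3e-09, and adjusted p = 0.149 with an estimated correlation). Stromal and endothelial markers rose in 8 of 13 (9 higher and 1 lower over the list alone; adjusted p = 3.05e-09, and adjusted p = 0.0892 with an estimated correlation). Neutrophil markers rose in 1 of 18 (0 over the list alone; adjusted p = 0.000542, 0.0719 without the arrays with low Pax5, and adjusted p = 0.535 with an estimated correlation). Stem and progenitor markers rose in 3 of 9, over the list alone as well; their adjusted p of 0.0373 became 0.106 and 0.0780 without array 4 or 5 of Bank1/Pax5 leukemia, 0.0801 with cyclic loess and 0.0518 with median centring, and adjusted p = 0.374 with an estimated correlation. NK cell markers fell in 5 of 11 (7 over the list alone; adjusted p = 0.00126, and adjusted p = 0.276 with an estimated correlation), with Klra8 at -2.55 (SE 0.28) and Eomes at -1.69 (SE 0.26), both dim in Bank1/Pax5 leukemia.

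The remaining lists did not pass, with adjusted p from 0.0636 to 0.979. Members called higher and lower were 1 and 3 of 19 mature B cell genes, 2 and 4 of 18 IL-7 receptor and survival genes, 0 and 3 of 18 p53 response genes, 2 and 5 of 22 NF-kB and inflammatory genes, 0 and 0 of 13 erythroid, 0 and 1 of 14 T cell, 1 and 3 of 9 plasma cell, 0 and 1 of 9 dendritic cell, and 0 and 0 of 9 mast cell, basophil and eosinophil markers. The median and mean differed in sign for mature B cell genes (0.06 and -0.19, test downward), p53 response genes (0.10 and -0.13, test upward), NF-kB and inflammatory genes (0.12 and -0.01, test upward) and plasma cell markers (0.28 and -0.06, test upward). The groups did not overlap for 3909 genes, 19.6% against 0.952% by chance. Median centring gave 1495 higher and 2099 lower, and cyclic loess 2079 and 1933, so the excess of lower genes depended on scaling; array weights gave 6486 calls and the replicate block 2542.

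Both leukemia groups shared many changes from WT: 883 genes were higher in both, 1615 were lower in both and 4 were called in opposite directions. Simulated unchanged groups with the same WT arrays shared 0.02 and 0.05 calls on average. Unchanged groups yield almost no calls at this threshold, so these averages cannot show what the common WT arrays add to the shared calls. Independent lists of the observed sizes would share 129 and 351. With separate WT arrays for each comparison, over 6 ways to divide them, 298 to 339 were shared higher and 699 to 747 lower. Ppbp, Bgn, Sparc, Vcam1 and Serping1 were among the top genes higher in both comparisons, and Xist, Reln, Polm, Eya1, Lgr5 and Fcrla among those lower. Across genes the log2 differences correlated at r = 0.835, against 0.165 in simulations of unchanged groups, and genes are not independent replicates. Array weights gave 4524 shared calls and the replicate block 1653. Both comparisons set total marrow, mostly with the male pattern of sex-linked genes, against a precursor fraction with the female pattern. Cell content, sample handling and sex can therefore be part of the shared changes, and they were not separated from leukemia.

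The comparison of Bank1/Pax5 with Pax5 leukemia addresses what a heterozygous Bank1 adds in leukemia with heterozygous Pax5. Rnase12 was lower in Bank1/Pax5 leukemia (log2 difference -4.52, SE 0.94, adjusted p = 0.0127, 6 arrays each), with 4 Bank1/Pax5 leukemias at 5.82 to 5.97 and 2 at 10.04 and 11.72, against 6.30 to 6.87 in WT. Rnase11, a gene of the same ribonuclease family, fell by 1.79 (SE 0.33, adjusted p = 0.00729), Rnf157 fell by 1.29 (SE 0.22, adjusted p = 0.00499) and P2rx3, which encodes an ATP-gated channel, fell by 1.71 (SE 0.33, adjusted p = 0.00880). Interferon-induced Rsad2 rose by 2.48 (SE 0.65, adjusted p = 0.0356) and the T cell receptor component Cd3g by 2.03 (SE 0.46, adjusted p = 0.0187), both dim in Pax5 leukemia (6.90 and 5.82), as Rnase11 was in Bank1/Pax5 leukemia (6.45). Rsad2 was at 9.40 in WT, against 9.39 in Bank1/Pax5 leukemia, and Cd3g was at 7.12 in WT, against 7.85. In all, 1336 genes were called, 340 higher and 996 lower, of which 31 and 42 differed at least 2-fold. The fit without WT had fewer false calls in simulations with each group's own spread (140 against 423), though not with 1 spread per gene (87 against 81). It called 446 genes, 87 higher and 359 lower, of which 443 were among the 1336.

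Of the 20 top genes, 3 were also called in the fit without WT: Rnase11 (adjusted p = 0.0364), P2rx3 (0.0406) and Rnf157 (0.0262). The others missed it at adjusted p from 0.0504 for Rnase12 to 0.115 for Tmem255a. These were, with log2 differences, Rsad2, Trim30d (2.42), Trim12a (2.23), Cd3g, Vsig4 (1.88), Zfp979 (1.72), Prrg4 (1.70), Adgre1 (1.69), Adgre4 (1.67) and Ccl5 (1.58) among the higher ones. Among the lower ones they were Rnase12, Padi2 (-1.92), Tmem255a (-1.88), Bank1 (-1.54), Bcat1 (-1.54), Sema7a (-1.52) and Vash2 (-1.50). Trim30d, Vsig4, Zfp979, Prrg4, Adgre1 and Adgre4 were dim in Pax5 leukemia, and Zfp979 and Vash2 in Bank1/Pax5 leukemia. The WT levels of Trim30d (8.66), Trim12a (10.17), Zfp979 (6.95), Prrg4 (8.04) and Ccl5 (10.95) lay nearer Bank1/Pax5 than Pax5 leukemia. Those of Vsig4, Adgre1 and Adgre4 lay nearer Pax5 leukemia. Within Pax5 leukemia Trim12a was split, at 6.04 to 6.10 on arrays 1, 3 and 5 and 7.99 to 8.81 on arrays 2, 4 and 6. Trim30d was at 7.65 and 7.66 on arrays 2 and 6 and at 5.21 to 5.98 on the other arrays of that group. Several calls ended when single arrays were left out. For Rsad2 these were arrays 1, 4, 5 and 6 of Bank1/Pax5 and 1, 2, 5 and 6 of Pax5 leukemia (adjusted p from 0.0556 to 0.0834), for Prrg4 arrays 3, 4 and 5 and all 6 (0.0553 to 0.0811), and for Adgre1 arrays 4, 5 and 6 and arrays 1, 2, 4 and 5 (0.0538 to 0.0667). For Ccl5 they were arrays 1, 3, 4, 5 and 6 and arrays 1, 2, 4, 5 and 6 (0.0508 to 0.0977), for Tmem255a arrays 1, 4, 5 and 6 and arrays 1, 2, 4, 5 and 6 (0.0665 to 0.0956), and for Vash2 arrays 1, 4, 5 and 6 and arrays 1, 2, 4 and 6 (0.0554 to 0.0790), in the same order of groups. The call of Trim30d ended without array 5 of Bank1/Pax5 leukemia (0.0569) or array 1 (0.0553), 4 (0.0555) or 5 (0.0583) of Pax5 leukemia, and that of Sema7a without array 5 of Bank1/Pax5 leukemia (0.0658) or array 2 (0.0577) or 6 (0.0517) of Pax5 leukemia. That of Bcat1 ended without array 4 (0.0536), 5 (0.0681) or 6 (0.0526) of Bank1/Pax5 leukemia or array 2 (0.0600) or 6 (0.0538) of Pax5 leukemia. The probe sets of P2rx3 gave -1.71 and -0.40.

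MYC targets and ribosome biogenesis genes were lower as a list in Bank1/Pax5 than in Pax5 leukemia (adjusted p = 9.65e-07), but not with an estimated correlation (adjusted p = 0.680). Of 20 members 7 fell and none rose (12 over the list alone), and 3 were called in the fit without WT: Cad, an enzyme of pyrimidine synthesis (-0.92, SE 0.16), and the nucleolar protein genes Ncl (-0.51, SE 0.10) and Nop56 (-0.62, SE 0.12). The level of the list was lowest on array 4 of Bank1/Pax5 leukemia (9.61; others 10.13 to 10.48), and all but array 4 lay within the range of Pax5 leukemia (10.11 to 10.77). Without array 4 the list passed (adjusted p = 9.46e-05). Non-B markers were higher in the same comparison. With them as a covariate the difference in level between the groups went from -0.285 (95% interval -0.648 to 0.078) to -0.135 (-0.580 to 0.310). Myc itself did not pass (-0.37, SE 0.15, adjusted p = 0.163), though it did without array 3 of Pax5 leukemia (-0.52, adjusted p = 0.00600). Cell cycle genes were shifted downward as a list while none of 27 passed alone (adjusted p = 0.000302, 0.0547 with dim probe sets removed, and adjusted p = 0.680 with an estimated correlation). The median level of the list was low on arrays 4 and 6 of Bank1/Pax5 leukemia alone (8.73 and 9.41), and the other 4 lay at 10.47 to 10.93 against 10.34 to 10.84 in Pax5 leukemia. Ikzf1, a leukemia suppressor gene, fell by 0.41 (SE 0.09, adjusted p = 0.0134).

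A further group, noticed only after the values were seen, was that of snoRNAs, which guide the modification of ribosomal and spliceosomal RNA. Of 53 measured snoRNA genes 30 fell and 1 rose in Bank1/Pax5 against Pax5 leukemia, with a median log2 difference of -0.592 (95% interval over genes -0.924 to -0.416), and 21 fell in the fit without WT. Among all other genes 4.86% were called lower, against 56.6% of snoRNAs (Fisher's exact test, p = 1.23e-25, genes not being independent). The largest falls were in Snord35a (-2.29, adjusted p = 0.000292) and Snord118 (-2.17, adjusted p = 0.0236), of which Snord118 was not called in the fit without WT (0.0708). The snoRNA level per array was 8.05 ± 0.43 (SD, n = 6) in Bank1/Pax5 leukemia, 9.03 ± 0.13 (SD, n = 6) in Pax5 leukemia and 8.34 ± 0.16 (SD, n = 4) in WT. All 6 Pax5 leukemias lay above all Bank1/Pax5 leukemias (exact two-sided permutation p = 0.00216, the smallest that 924 splits can give). Pax5 leukemia also lay above WT (0.694, exact permutation p = 0.00476), whereas Bank1/Pax5 leukemia differed from WT by -0.289 (exact permutation p = 0.233). The direction held with median centring (26 lower, 1 higher) and cyclic loess (25 lower, 1 higher). Over the leukemia arrays the snoRNA level was lower where non-B markers were higher. With these as a covariate the difference between the groups went from -0.983 (95% interval -1.396 to -0.571) to -0.655 (-1.014 to -0.295). In the fit per gene with that covariate 14 snoRNAs were lower and 1 higher.

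Marker lists of 5 other cell types were higher in Bank1/Pax5 than in Pax5 leukemia, but none with an estimated correlation (adjusted p = 0.680 for each). NK cell markers rose in 3 of 11 (8 over the list alone), Eomes, Klrk1 and Prf1 (0.92, 1.33 and 0.44), all dim in Pax5 leukemia, and none of these was called without WT (adjusted p from 0.0507 to 0.101). Their calls also ended without arrays 4, 5 and 6 of Bank1/Pax5 leukemia (array 3 too for Prf1) and arrays 2 and 6 of Pax5 leukemia, without arrays 1 and 5 for Eomes and Klrk1, 4 for Prf1 and Klrk1 and 3 for Klrk1 (adjusted p from 0.0535 to 0.106). T cell markers rose in 2 of 14 (3 over the list alone) and monocyte and macrophage markers in 1 of 15, over the list alone as well. No erythroid marker of 13 and no megakaryocyte marker of 9 passed alone. The list tests gave adjusted p of 0.000302 for NK, 0.00528 for T, 0.00307 for monocyte and macrophage, 0.000363 for erythroid and 0.0286 for megakaryocyte markers, all upward. The erythroid level was raised on arrays 1, 4 and 5 of Bank1/Pax5 leukemia (9.86, 8.09 and 8.96), while arrays 2, 3 and 6 (6.56, 6.39 and 6.77) lay within the range of Pax5 leukemia (6.39 to 7.35). The megakaryocyte level of arrays 2, 3 and 6 (8.95, 8.91 and 9.78) also lay within that range (8.17 to 10.17). The T cell list missed the test with dim probe sets removed (0.0959), and without the arrays with low Pax5 so did the monocyte (0.0567), erythroid (0.0637) and megakaryocyte (0.275) lists. The megakaryocyte call also ended without array 1 (0.0737), 4 (0.123), 5 (0.125) or 6 (0.0523) of Bank1/Pax5 leukemia or array 1 (0.213), 2 (0.0819) or 4 (0.0888) of Pax5 leukemia. Interferon response genes shifted upward, with 1 of 18 called, over the list alone as well (adjusted p = 0.00106, and adjusted p = 0.680 with an estimated correlation). Arrays 2 and 3 of Bank1/Pax5 leukemia (7.15 and 8.72) lay within the range of Pax5 leukemia (6.67 to 8.96).

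The remaining lists did not pass, with adjusted p from 0.0847 to 0.998. Called lower were 2 of 19 mature B cell genes (Cd37 and Tnfrsf13c), 2 of 21 B cell receptor signalling genes (Bank1 and Plcg2), 2 of 18 leukemia suppressor genes (Bank1 and Ikzf1), 1 of 18 p53 response genes (Mdm2) and 1 of 21 oxidative phosphorylation genes (Atp5b). Of these, Mdm2 missed with cyclic loess (adjusted p = 0.367) and without arrays 5 and 6 of Bank1/Pax5 and 1, 3, 5 and 6 of Pax5 leukemia (0.0518 to 0.0725), and Tnfrsf13c without arrays 1, 4, 5 and 6 and arrays 1, 2, 4, 5 and 6 (0.0584 to 0.0835). Cd37 missed without array 5 of Bank1/Pax5 leukemia (0.0585) or array 4 of Pax5 leukemia (0.0537). Called higher were 1 of 14 glycolysis genes (Hk1) and 1 of 9 dendritic cell markers (Batf3). Hk1 missed with median centring (adjusted p = 0.0739), and Batf3 with cyclic loess (0.0518) and without arrays 2, 4 and 5 of Bank1/Pax5 and 2, 3, 4, 5 and 6 of Pax5 leukemia (0.0502 to 0.102); neither was called in the fit without WT (0.0708 and 0.117). No member was called among 18 Pax5-activated, 15 Pax5-repressed, 19 pro-B and pre-B stage, 18 IL-7 receptor and survival, 22 NF-kB and 19 immediate early genes, nor among 18 neutrophil, 9 plasma cell, 9 mast cell, basophil and eosinophil, 13 stromal and endothelial, and 9 stem and progenitor markers. The median and mean differed in sign for p53 response (-0.01 and 0.03, test downward) and oxidative phosphorylation genes (0.03 and -0.07, test downward).

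The leukemia groups did not overlap for 539 genes, 2.70% against 0.216% by chance. The count was 725 without array 5 of Bank1/Pax5 leukemia, 870 and 846 without array 4 or 5 of Pax5 leukemia, 696 with the replicate block, 659 without the arrays with low Pax5 and 291 with non-B markers as a covariate. Cyclic loess gave 452 higher and 618 lower, and median centring 271 and 873.

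**Figure D2:**
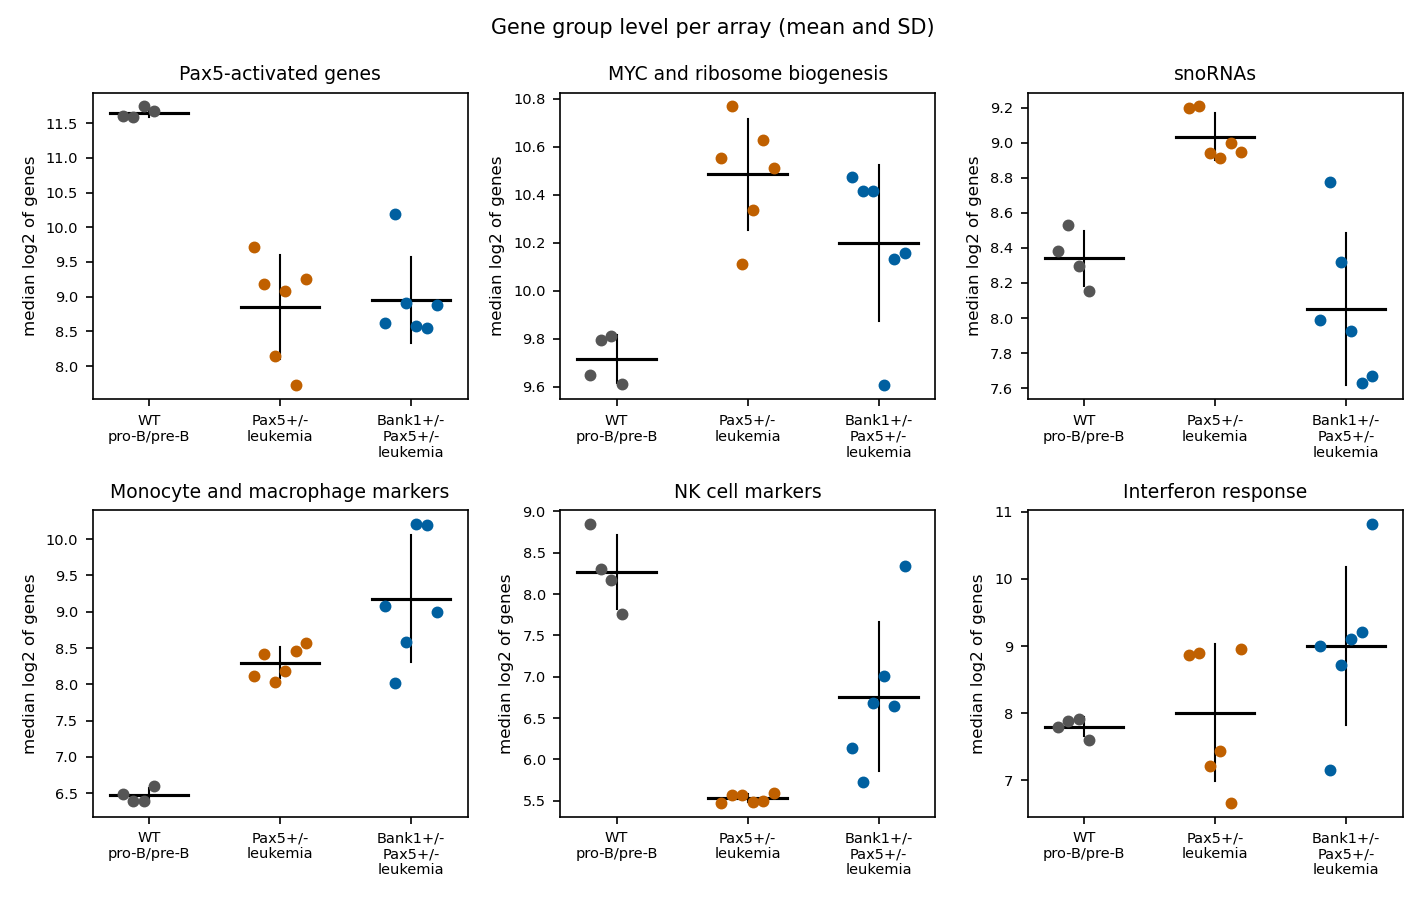
Median log2 expression of 6 gene groups on each array (points), with group means (horizontal bars) and SDs (vertical lines). Pax5-activated genes averaged 11.65 in WT and 8.85 and 8.95 in Pax5 and Bank1/Pax5 leukemia, and snoRNAs averaged 9.03 in Pax5 leukemia and 8.05 in Bank1/Pax5 leukemia.

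Sex-linked genes differed between arrays within the leukemia groups. Xist was high on arrays 3 and 5 of Bank1/Pax5 leukemia (12.81 and 12.46) and at 9.96 on array 2 of Pax5 leukemia, where Eif2s3y was at 4.54 to 4.62, while the other leukemia arrays had Eif2s3y at 9.30 to 10.09. The log2 differences of Uty, Kdm5d, Eif2s3y and Xist between the leukemia groups did not pass (adjusted p from 0.467 to 0.678). Of 11 immunoglobulin segments, 1 was lower in Pax5 leukemia than WT, 1 was higher in Bank1/Pax5 leukemia than WT and 1 was higher in Bank1/Pax5 than in Pax5 leukemia. Igha, the IgA constant region, was the one lower in Pax5 leukemia than WT (-1.99, adjusted p = 0.0162) and higher in Bank1/Pax5 than in Pax5 leukemia (2.08, adjusted p = 0.0218), and Igkv4-91 was the one higher in Bank1/Pax5 leukemia than WT (1.72, adjusted p = 0.0288; dim in WT). Igha missed against WT without WT array 4 (0.0522), and between the leukemia groups in the fit without WT (0.0712) and without the arrays with low Pax5 (0.113). Igkv4-91 missed without array 1 (0.0533) or 3 (0.0523) of Bank1/Pax5 leukemia and without WT array 1 (0.0731), 2 (0.0609), 3 (0.0658) or 4 (0.0646).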

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

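The tests of NK markers against a general loss of other cells, of snoRNAs against their own hosts and non-B cells and of the non-B markers were chosen only after the results were seen, while the other tests here were set before.

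Single arrays stood apart from the rest of their group in 39 of 432 groups of values tested, where chance alone gives about 21.6 (1 in 20). On Pax5 leukemia array 1 these were Rnase12 at 10.33 (others 12.23 to 12.55), Lgr5 at 8.76 and Enpep at 6.94. On Pax5 leukemia array 2 they were Eif2s3y at 4.59, Uty at 4.78, Kdm5d at 4.86 and Xist at 9.96, the reverse of the other arrays of that group. Pax5 leukemia array 3 had Pax5 at 7.52 (others 11.14 to 12.21), Tmem255a at 6.99, Nop56 at 11.31, Pdk1 at 8.85, dendritic cell markers at 8.19 and mast cell, basophil and eosinophil markers at 6.88. P2rx3 was at 7.26 on Pax5 leukemia array 4, Hk1 at 13.04 on array 5, and Ikzf1 was at 10.89 and stem and progenitor markers at 6.98 on array 6.

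In Bank1/Pax5 leukemia, array 2 had Lgr5 at 8.92, Ifitm1 at 9.75, Vash2 at 7.80, Pax5-activated genes at 10.19 (others 8.55 to 8.91) and Pax5-repressed genes at 8.79 (others 10.05 to 10.45). Array 4 had Fabp4 at 11.44, Prkcb at 10.65 and Srm at 10.20, and array 5 had Rnase11 at 7.06. Array 6 had Trim12a at 10.65, Prrg4 at 10.38, mature B cell genes at 9.68 and dendritic cell markers at 9.13. Among WT arrays, array 1 had Igkv4-91 at 5.93, array 2 had Bcat1 at 9.5, Myc at 9.87, Btg1 at 12.48 and Ikzf1 at 11.57, array 3 had plasma cell markers at 9.60, and array 4 had Cd3g at 6.59, Kit at 7.23 and Rtp4 at 6.25.

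The change from WT differed between the leukemia genotypes for 1336 genes. This is the contrast of the leukemia groups given above, since WT cancels out of it, and not a separate result. The fit without WT called 446 genes. Probe sets outside the comparisons also carried signal: of 12146 without a gene name, 2550, 2573 and 1156 were called in Pax5 leukemia against WT, Bank1/Pax5 leukemia against WT and between the leukemia groups. Of 1621 naming several genes, 370, 335 and 94 were called.

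Chance as the source of the calls was examined by regrouping arrays, with 100 splits drawn for each comparison. In each, only 1 split, the real one, gave as many genes. The real counts of 4655, 3899 and 1336 stood against 1679, 978 and 920 for the highest other split. Chance as the source of these counts is therefore argued against, to no finer than 1 in 100 splits. Regrouping arrays cannot separate genotype from sex, cell content or batch. The split with 920 genes kept 5 of the 6 Bank1/Pax5 leukemias together and added Pax5 leukemia array 3, which had low Pax5.

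The lower snoRNAs of Bank1/Pax5 leukemia were weighed first. For a poorer recovery or labelling of short RNA in general, 62 other short RNA genes above the median level were examined. Their median log2 difference was 0.048 (95% interval over genes 0.011 to 0.118), against 0.016 over all genes. This argues against such a loss only as far as these genes read above background, which was not measured. These genes are of other classes, so a technical effect limited to RNA of snoRNA size was not tested. Lower host genes as the whole source are also argued against, for the 31 of 53 snoRNAs with a measured host. The snoRNAs of 27 measured hosts differed from their own host by a median of -0.235 (95% interval over hosts -0.631 to -0.102). That interval does not carry the spread between arrays. Hosts were genes whose span holds the snoRNA, on either strand. SnoRNAs without a measured host, Snord35a and Snord118 among them, are not covered. As a part of the source host genes stay open. The hosts had a median of -0.114 (-0.327 to -0.001), short of the -0.592 of the snoRNAs, but the interval reached the bound of -0.296 set beforehand. More non-B cells, as the mean of 8 marker lists measures them, are argued against as the whole source, since the difference with them as a covariate was -0.655 (95% interval -1.014 to -0.295), but they may be a part of it (-0.404 per log2 unit of the markers, -0.668 to -0.141). A link to MYC and ribosome biogenesis genes also stays open, with a within-group r of 0.465 over 12 arrays (permutation p = 0.224, adjusted 0.224; rho 0.776, permutation p = 0.00700, adjusted 0.0140; r 0.634 without the 2 arrays farthest from the median). The heterozygous Bank1 remains an untested candidate explanation.

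The higher NK markers of WT cells were weighed second. Whether leukemic marrow lost non-B cells of every type cannot be decided here. Monocyte and macrophage markers were higher in both leukemia groups, the smaller median being 1.57. The WT samples are a B cell precursor fraction, however, so these markers may be low there through isolation. The values show only that the excess in WT did not extend to monocyte and macrophage markers. NK cells among the WT cells may contribute: a second list of 18 NK genes, none of them in the first, was higher in WT by a median of 0.883 (95% interval 0.236 to 1.285), 16 of them higher. That median fell between the bounds set beforehand, so NK cells and a lower expression of these genes in leukemia cannot be told apart, and any gate used on the WT cells is not given in the sources used here.

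The higher non-B markers of Bank1/Pax5 leukemia were weighed last, with the mean of 8 non-B lists 0.813 higher (exact permutation p = 0.0476, 6 arrays each). Without the 2 highest arrays it was 0.441 higher (exact permutation p = 0.190), so a few arrays as the source stay open. A lower share of leukemic cells may account for it. The NK list rose by 1.092 more than the stromal list (exact permutation p = 0.0238), but that pair was picked as the extremes of the 8 lists, and the gap between extremes has an exact permutation p of 0.576. A lower leukemic share and a change in particular cells therefore cannot be told apart.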

How the results depend on the processing

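The covariates of Y-linked genes and non-B markers and the omissions of arrays with low Pax5 and of short RNAs were chosen after seeing the data. Where no cause is stated, the cause was not tested. Of the main results under settings other than single omissions, 109 kept direction and side of the threshold (counts: stayed within 1.5-fold), 16 moved, 4 became stronger, 4 weaker and 2 reversed; of other results 2159 were kept, 234 weakened, 9 strengthened and 8 reversed. Over single omissions 134 main results were kept, 4 moved, 2 became stronger and 4 weaker, and of other results 2353 were kept, 16 strengthened and 235 weakened. Signal over background was not measured, so dim genes limit the comparisons to an unknown extent.

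Genes changed in Pax5 leukemia against WT numbered 4655, 8104 with array weights, 972 at least 2-fold and 3072 (without WT array 4) to 5560 over single omissions. For Bank1/Pax5 leukemia against WT they numbered 3899, 6486 with array weights, 2542 with the block, 936 at least 2-fold and 2678 to 4531 over omissions. Between leukemias they numbered 1336, 446 with only those groups, 696 with the block, 73 at least 2-fold, 659 without low Pax5, 291 with the non-B covariate and 725 to 1742 over omissions, with 725 without Bank1/Pax5 array 5 and 870 and 846 without Pax5 leukemia array 4 or 5. Genes called in both leukemias (883 higher, 1615 lower) numbered 4524 with array weights, 1653 with the block, 577 at least 2-fold and 1711 to 2883 over omissions. Counts at least 2-fold are lower by construction. The size of a count says nothing about its direction: more genes were higher than lower in Pax5 leukemia against WT with median centring, cyclic loess, dim probe sets removed or a 2-fold minimum, and in Bank1/Pax5 leukemia against WT with cyclic loess or a 2-fold minimum. Replicate numbers were not taken as pairs: arrays of the same number correlated above 0.1 in 1 of 4, 3 of 4 and 2 of 6 pairs in the order of these comparisons, and they were the best match in only 1, 2 and 0.

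Bank1 in Pax5 leukemia against WT (1.01) was 1.13 with array weights (adjusted p = 0.00644), 1.81 with the Y covariate (0.0222) and 0.83 to 1.28 over omissions, passing without Pax5 leukemia array 1 (0.0189). In Bank1/Pax5 leukemia (-0.53) it was 0.0688 with the Y covariate (0.933) and -0.71 to -0.26 over omissions. Between leukemias (-1.54) it missed the threshold at -1.54 with only those groups (0.0815), -1.54 with the block (0.0609), -1.76 without low Pax5 (0.0662) and -1.61 with the non-B covariate (0.111), with -1.82 to -1.27 over omissions. Pax5 against WT was -1.22 to -0.29 over omissions in Pax5 leukemia. In Bank1/Pax5 leukemia it passed with array weights (-2.50, 0.0124), without low Pax5 (-1.26, 0.0407) and without array 2 (-2.59, 0.0446), with a range of -2.59 to -1.79. The pass without low Pax5 follows a selection of arrays on Pax5 itself. Between leukemias Pax5 was 0.45 with the non-B covariate (0.755) and -1.89 to -0.81 over omissions.

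Gene lists past the test numbered 10, 17 and 8, and 1, 0 and 0 with an estimated correlation; over omissions they numbered 10 to 12, 16 to 19 and 7 to 12. Eif2s3y, Kdm5d and Uty make up the Y covariate, so their loss under it is by construction and says nothing about them: Eif2s3y became -0.05 in Pax5 leukemia against WT and 0.20 between leukemias, Kdm5d -0.0205 in Pax5 and -0.0895 in Bank1/Pax5 leukemia against WT, and Uty -0.0126 in Bank1/Pax5 leukemia against WT. Also reversed were Batf3 with that covariate (-0.0071, Bank1/Pax5 leukemia against WT) and, with the non-B covariate between leukemias, Ppbp (-0.0522) and Slamf1 (-0.33). Ppbp belongs to the megakaryocyte list, which is among the 8 lists of the non-B covariate, so its reversal is partly by construction.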

Other observations

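The tests of Pax5-activated genes and of the neighbours of Bank1 were set before their results were seen, and the comparisons of snoRNAs with WT, like the genes of the second NK list described here, were chosen after values were seen.

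Against WT, snoRNA genes went separate ways in the leukemia groups. In Pax5 leukemia 32 of 53 rose and 3 fell, with a median log2 difference of 0.623, and in Bank1/Pax5 leukemia 8 rose and 9 fell, with a median of 0.010. The direction in Pax5 leukemia was kept with median centring (0.665) and cyclic loess (0.662).

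Further genes known from NK and T cells were higher in WT precursors than in leukemia. Klri2 was at 7.58 in WT and 5.58 in leukemia, Xcl1 at 8.18 and 6.53, and Ifng, the gene of interferon gamma, at 6.98 and 6.06. All 3 were dim in leukemia and Ifng in WT as well, so the sizes are not well bounded. Each was called lower in both leukemia groups, with adjusted p in Pax5 and Bank1/Pax5 leukemia of 1e-04 and 0.000256 for Klri2, 0.000598 and 0.0172 for Xcl1 and 2.27e-05 and 0.000103 for Ifng. The call of Xcl1 in Bank1/Pax5 leukemia was lost without WT array 1 (0.0645). Of the 18 genes of that list, 14 were called lower in Pax5 leukemia and 9 in Bank1/Pax5 leukemia, while Sh2d1b1 was higher in Bank1/Pax5 leukemia (adjusted p = 0.0274).

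One hypothesis was that Pax5-activated genes follow the Pax5 level among leukemias, 3 of which had low Pax5. Over the 12 leukemia arrays r was 0.510 (permutation p = 0.0898, adjusted 0.180 over 2 relations) and rho was 0.650 (permutation p = 0.0260, adjusted 0.0260). Without the 2 arrays farthest from the median Pax5 level r was 0.379, and among the 9 arrays with higher Pax5 it was 0.326 (exact permutation p = 0.401; rho 0.567, exact permutation p = 0.121). The relation may hold but rests partly on the arrays with low Pax5. Of these, arrays 1 and 5 of Bank1/Pax5 leukemia had the highest means of the 8 non-B lists among leukemias (8.73 and 9.14). Array 3 of Pax5 leukemia was at 7.78, against 6.95 to 7.93 in its group. Cell content was not separated from the Pax5 level, so the relation alone does not show a dependence on Pax5.

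Another hypothesis was that passenger variants beside the Bank1 allele add genes changed between the leukemia groups. Of the 40 measured neighbours of Bank1, 4 were called (Gstcd, Ube2d3, Lamtor3 and Adh5), 10% against 6.69% elsewhere (Fisher's exact test, one-sided, p = 0.278), which neither shows nor excludes it.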
